A study of Mus musculus with 24 samples.

How the data were processed

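Gene expression was measured on 24 microarrays of mouse bone marrow cells. Per the labels, lineage-negative Sca-1+ Kit+ (LSK) cells of C57BL/6 mice, a population rich in blood stem and progenitor cells, were cultured with the cytokines IL3, IL6, SCF and FLT3 ligand and infected with retroviruses. One virus carried BCR-ABL, the tyrosine kinase fusion of chronic myeloid leukaemia, with green fluorescent protein. The other carried NUP98-HOXA9, a fusion of a nuclear pore protein with a homeobox transcription factor, with yellow fluorescent protein. The cells were transplanted, and after 9 days in vivo lineage-negative marrow cells were sorted by their fluorescence into 4 groups (neither oncogene, BCR-ABL, NUP98-HOXA9, or both) with 6 arrays each. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 6 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

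The authors deposited linear intensity values, 1 for each of 45101 probe sets on each array. Per the labels' protocols, RNA was purified with a column kit, amplified and labelled as biotinylated cDNA with a NuGEN kit, and hybridised to an Affymetrix mouse genome array with 1 colour. How the probe signals were summarised, corrected for background and scaled between arrays is not given in the sources used here. The values ran from 0.56 to 17783.11, between 245 and 491 values on each array were exactly 1, and the array medians lay between 50.41 and 64.90, so the arrays had not been set to a common median. No further scaling was applied for the reported results. The number of arrays limits the precision.

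Of the probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 were listed with none. Symbols came from the platform's annotation, and 34741 of the probe sets with 1 symbol matched a mouse gene table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols. Probe sets with several symbols or none entered no gene comparison. For the 9010 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 18193 genes. Ly6a, the gene of Sca-1, had no probe set of its own and was not analysed here. Probe sets of Hoxa9 and Nup98 were also read separately.

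Intensities were converted to log2 without a pseudocount. A linear model with 4 group means was fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of data.table. The model had 20 residual and 1.41 prior degrees of freedom. Each of the 6 comparisons of 2 groups, and the interaction (both minus BCR-ABL minus NUP98-HOXA9 plus neither, on the log2 scale), was adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05 on adjusted p. All tests were two-sided. Errors given with a fold change are standard errors of this fit, and those given with a level are standard deviations over 6 arrays. A gene was counted as beyond either oncogene when the group with both differed past the threshold and in 1 direction from each of the other groups. A cooperation ratio was also taken, over genes past the threshold in both against neither, from the linear group means: the sum of the single-oncogene means over the mean in both for genes that rose, and the sum of the ratios of both to each single-oncogene mean for genes that fell, with a limit of 0.9.

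The array background was set at the 95th percentile of 27 control probe sets for Bacillus transcripts, 17.75 in linear intensity or 4.15 on the log2 scale. Where the lower group of a comparison lay at or under it on all 6 arrays, the change is given as at least N-fold, the geometric mean of the higher group over that of the lower group with each value raised to the background, with the fit's adjusted p. No fold is given where this bound was under 1. Values at or under the background are called at background, and values so raised are called raised values. Where only some of the 6 arrays were at background, their number is given with the fold of the raised values, the raised fold.

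Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 25 lists within each comparison. The lists covered stem cell markers, oncogene pathways, lineage and other cell type markers, immune, stress and metabolic genes, and each is named with its results. They held 500 memberships, of which 452 were measured over 437 distinct genes, and 15 genes were in more than 1 list. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in 1 direction. In 12 of the list comparisons the median, mean and test differed in sign, and 1 of these was called. Counts of members past the threshold are given as adjusted over all genes and as adjusted over the list alone.

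Genes were named by a rule: the 7 largest rises and the 7 largest falls past the threshold in each comparison (10 each for the interaction), leaving out clone and model names; for each list described, members with the largest change past the threshold and, as an example that did not pass, its member with the highest level; and Hoxa9, Nup98, Bcr, Abl1, Meis1, Kit, Cd34, Msi2 and Numb throughout. Named genes whose probe sets disagreed in sign are given with the other settings.

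The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The background level, the list of array checks, the level filter of the principal component analysis (12898 genes), the setting with values raised to the background the count without NUP98-HOXA9 replicate 2 and the test of Hoxa9 in 2 groups alone were chosen after the values were seen. The alternatives were the mean of all probe sets of a gene, every probe set counted on its own, quantile normalization, a common median or 75th percentile, eBayes with trend and robust options, array weights, a filter on dim genes (above the 40th percentile of all values, 5.72 on the log2 scale, on at least 6 arrays, which kept 11353 genes), a 2-fold minimum, only the groups compared, the replicate number as a fixed or random block, and each array left out in turn.

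The fit was tested on simulated data with 200 changed genes drawn over the real group means and spreads. In simulated BCR-ABL against neither, the shares recovered were 29.9% of genes changed by 0.5 (log2), 56.7% by 1 and 97% by 2, over 18193 genes. In simulated both against BCR-ABL the shares were 35.8%, 62.7% and 87.9%, and for a simulated interaction 31.3%, 43.3% and 74.2%. Unchanged genes made up 4.69%, 8.82% and 4.81% of these calls, none of which had the wrong sign, and on average 4.94%, 5.73% and 4.81% over 20 further draws. In the list test, a list shifted by 0.5 was called and 0 of 24 others were, but correlated genes were not tested.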

Results

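Gene expression was measured in lineage-negative mouse bone marrow cells after infection with retroviruses carrying BCR-ABL and NUP98-HOXA9 and 9 days in vivo. The cells were sorted into neither oncogene, BCR-ABL, NUP98-HOXA9 and both, with 6 arrays per group and 24 in all. The median probe set intensity was 60.16 ± 4.07 (SD, n = 6) in neither, 56.78 ± 3.69 in BCR-ABL, 59.49 ± 2.59 in NUP98-HOXA9 and 54.88 ± 1.48 in both, and single arrays lay between 50.41 and 64.90. The share of the 18193 genes above the array background was 71.56%, 72%, 71.05% and 72.1% in these groups. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 1.501, 1.526, 1.552 and 1.479. Arrays of 1 group correlated at 0.961 to 0.9859 across genes.

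The arrays separated by BCR-ABL first. On principal component 1, with 42.94% of the variance of 12898 genes, the mean score was -42.8 ± 7.57 (SD, n = 6) in neither, -22.15 ± 24.8 in NUP98-HOXA9, 35.8 ± 9.67 in BCR-ABL and 29.16 ± 4.94 in both. NUP98-HOXA9 replicate 2 had a score of 23.127, while the other arrays of its group lay between -43.2 and -17.687.

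**Figure D1:**
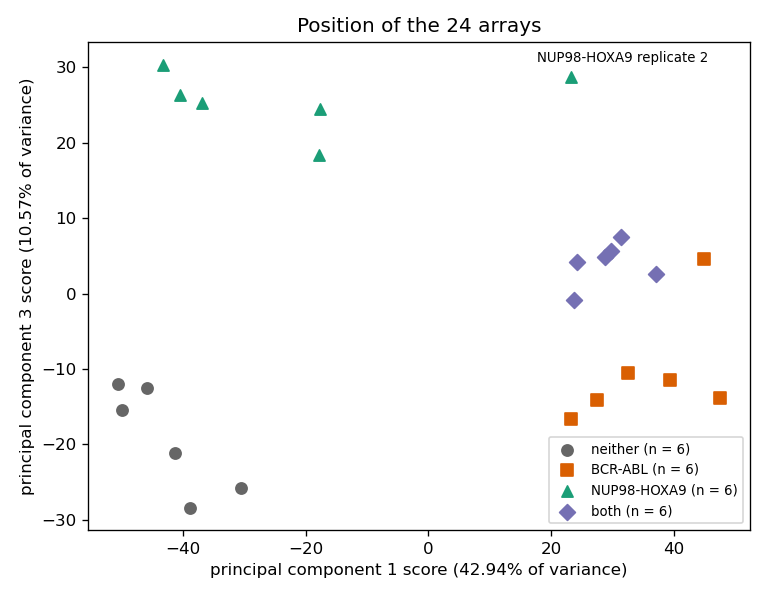
Scores of the 24 arrays on principal component 1 (x axis, 42.94% of the variance) and component 3 (y axis, 10.566% of the variance), with 1 point per array and 6 arrays per group. NUP98-HOXA9 replicate 2 lies apart from its group on component 1, at 23.127, and within it on component 3, at 28.7.

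The levels of the genes that contribute to the fusions were read first. Hoxa9 had a mean log2 level of 11.74 ± 0.29 (SD, n = 6) in neither, 11.95 ± 0.07 in BCR-ABL, 12.34 ± 0.10 in NUP98-HOXA9 and 12.12 ± 0.04 in both. It rose by 0.59 (SE 0.09, adjusted p = 0.000312) with NUP98-HOXA9 and by 0.38 (adjusted p = 0.00519) with both, while the change with BCR-ABL was 0.21 (adjusted p = 0.104). A second Hoxa9 probe set, with levels of 9.64, 10.11, 10.91 and 10.81 in the same order, rose by 1.26 with NUP98-HOXA9, or 2.4-fold (SE 0.15, adjusted p over all probe sets = 4.24e-05), by 1.17 with both (adjusted p = 1.90e-05) and by 0.47 with BCR-ABL (adjusted p = 0.0338). The brighter Nup98 probe set, with levels between 11.79 and 11.85, did not pass the threshold in any comparison, and a dimmer one, between 7.86 and 8.18, was higher in BCR-ABL than in NUP98-HOXA9 (0.32, adjusted p = 0.0209). Bcr levels were 10.70, 10.53, 10.88 and 10.62, and Abl1 levels were 10.00, 9.92, 9.84 and 9.71. Against neither, Abl1 fell with both (log2 -0.29, adjusted p = 0.0146) and had values of -0.09 and -0.16 with BCR-ABL and NUP98-HOXA9 (adjusted p = 0.49 and 0.32). The labels do not say whether these probe sets read the retroviral transcripts, so they do not check the sort.

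**Figure D2:**
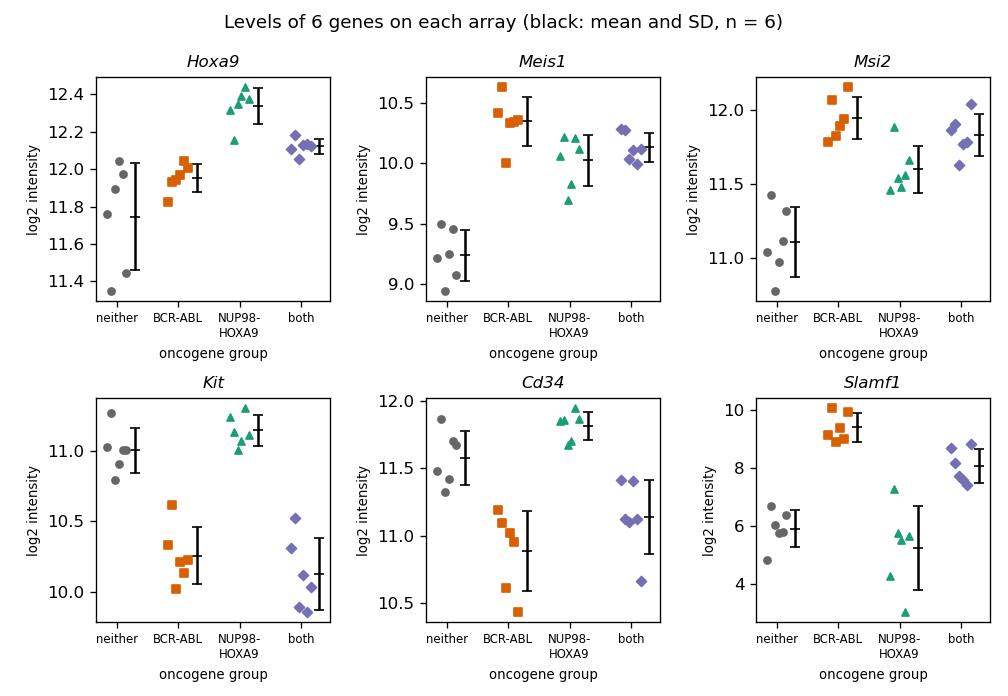
Log2 intensity (y axes) of Hoxa9, Meis1, Msi2, Kit, Cd34 and Slamf1 in the 4 oncogene groups (x axes), with 1 point per array and the mean and SD of 6 arrays in black. Meis1 had a mean of 9.24 in neither and from 10.02 to 10.35 with an oncogene.

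BCR-ABL cells were compared with neither. No group had a virus without an oncogene, so comparisons with neither may hold effects of infection or cell origin besides those of an oncogene. More members of the megakaryocyte, erythroid, stem cell and p53 lists rose than fell, and more members of the monocyte, neutrophil, interferon, MHC class II, B and T and NK lists fell than rose. Camera called 17 of 25 lists, 8 higher and 9 lower, of which 0 held with an estimated correlation. Of 18193 genes, 2469 rose and 2441 fell, and 1471 changed at least 2-fold. Meis1, the HOXA9 cofactor, rose by 1.11 on the log2 scale (SE 0.11, adjusted p = 5.07e-07) and Msi2, an RNA-binding regulator of stem cell fate, by 0.84 (SE 0.10, adjusted p = 3.97e-06). Kit, the stem cell factor receptor, fell by 0.75 (SE 0.11, adjusted p = 3.40e-05) and Cd34, a progenitor surface protein, by 0.69 (SE 0.13, adjusted p = 0.000476). Numb, a cell fate determinant, fell by 0.62 (SE 0.23, adjusted p = 0.0471), a call lost when any of 14 single arrays was left out (adjusted p = 0.12 without BCR-ABL replicate 2) and with values raised to the background (0.0509). Nup98 and Bcr had changes of 0.04 and -0.17 (adjusted p = 0.66 and 0.105).

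The largest rises with BCR-ABL were those of Psg17, a pregnancy-specific glycoprotein (log2 6.43, SE 1.13, adjusted p = 0.00021), the growth factor gene Gdf10 (5.59, SE 0.61, adjusted p = 1.29e-06), Ncam2 (5.48, SE 0.52, adjusted p = 3.03e-07) and the receptor phosphatase gene Ptprg (4.83, SE 0.85, adjusted p = 0.000213). In neither, 4, 4, 5 and 1 arrays lay at background for these genes (raised folds 32.1, 23.7, 21.5 and 25.2). The mast cell protease gene Mcpt1 was at least 13.1-fold higher (adjusted p = 1.65e-06), Ptprz1 at least 8.89-fold (adjusted p = 0.000249) and Erc2 at least 6.44-fold (adjusted p = 9.02e-06). Among the largest falls were an immunoglobulin light chain segment, Igkv6-15 (log2 -5.13, SE 0.75, adjusted p = 3.06e-05), the T cell receptor component Cd3e (-4.78, SE 0.59, adjusted p = 4.62e-06) and Tbx21, a T and NK cell transcription factor (-4.75, SE 0.74, adjusted p = 6.24e-05), for which 5, 4 and 5 of the BCR-ABL arrays lay at background (raised folds 10.4, 15.2 and 6.9). Klrc1, an NK receptor gene, was at least 13.6-fold lower (adjusted p = 6.53e-08), the chemokine receptor gene Cxcr6 at least 8.69-fold (adjusted p = 5.79e-05), Mmp13 at least 7.25-fold (adjusted p = 1.56e-07) and Plg at least 2.38-fold (adjusted p = 4.33e-07).

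Among the stem and multipotent progenitor markers, 11 of 21 measured genes rose and 4 fell with BCR-ABL (11 and 5 adjusted over the list alone). Slamf1, a surface marker of long-term stem cells, rose by 3.48, Mycn by 1.60 and Mllt3 by 1.57, and Fgd5 was at least 1.31-fold higher. Ifitm1, the member with the highest level, had a change of 0.07 (adjusted p = 0.472). The list was higher by camera (median 0.79, adjusted p = 0.00426; adjusted p = 0.289 with an estimated correlation, written p(est) below). Of the HOXA9 and MEIS1 programme, 6 of 21 rose and 5 fell (8 and 7 adjusted over the list alone). Hoxa10 rose by 1.23 (adjusted p = 4.10e-08) and Cd28 fell (log2 -2.06). The list was not called (median 0.04, adjusted p = 0.354). Of 17 STAT5 targets 8 rose and 4 fell (9 and 4 adjusted over the list alone). The interleukin 2 receptor gene Il2ra rose by 3.77 (adjusted p = 0.000192) and the feedback inhibitor Socs2 by 1.93, Bcl6 fell (log2 -1.73), and Pim1 had a change of 0.02. The STAT5 list was higher (median 0.19, adjusted p = 0.0407, p(est) = 0.289). The call was lost with raised values (adjusted p = 0.0696) and without neither replicate 2, BCR-ABL replicate 3 or BCR-ABL replicate 5 (highest adjusted p = 0.0965). Of 17 RAS-ERK targets 9 rose and 1 fell (10 and 1 adjusted over the list alone). The feedback inhibitors Spry4 (2.70, with 1 array of neither at background, raised fold 6.29) and Spry1 (2.36) led, while Fos had a change of -0.66 (adjusted p = 0.259). That list was higher as well (median 0.47, adjusted p = 0.000593, p(est) = 0.289).

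Of 16 megakaryocyte and platelet genes 10 rose with BCR-ABL and 0 fell (10 and 1 adjusted over the list alone). They included the platelet glycoprotein genes Gp1bb (2.77) and Gp5 (2.69) and the platelet chemokine gene Ppbp (2.57). The list median was 1.79 (adjusted p = 6.60e-07, p(est) = 0.289). Of 21 erythroid genes 10 rose and 0 fell (13 and 0 adjusted over the list alone). They included the erythropoietin receptor gene Epor (2.28), Rhag (2.18) and the erythroid transcription factor Klf1 (2.03). Tfrc had a change of 0.02 (list median 1.14, adjusted p = 3.83e-05, p(est) = 0.289). Of 19 monocyte and dendritic markers 12 fell and 0 rose (12 adjusted over the list alone). The transcription factor Irf8 fell (-2.11), as did F13a1 (-1.79), Cd209a was at least 5.05-fold lower, and Lyz2 had a change of -0.24 (adjusted p = 0.119; list median -0.72, adjusted p = 1.18e-06, p(est) = 0.289). Of 17 late neutrophil genes 8 fell (12 adjusted over the list alone). The largest falls were those of the granule proteases Mmp9 (-3.21) and Mmp8 (-2.25). S100a9 had a change of 0.05 (list median -0.45, adjusted p = 0.000381, p(est) = 0.404). Of 13 early granulocyte genes 9 fell (9 adjusted over the list alone), including Igsf6 (-0.91), Cebpa (-0.71) and Gfi1 (-0.50), with a median of -0.19 (adjusted p = 0.000161, p(est) = 0.289). Of 17 mast cell genes 5 rose and 5 fell (5 and 6 adjusted over the list alone). The protease genes Cma1 and Gzmb rose (3.86 and 2.60) and the IgE receptor gene Fcer1a fell (-2.86). The list was not called (adjusted p = 0.883).

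Some markers of other cell types fell beside these genes. Of 17 T and NK genes 8 fell and 1 rose (9 and 1 adjusted over the list alone). They included the cytotoxic granule gene Gzma (-3.60) and Klrd1 (-3.48), and the NK receptor gene Ncr1 was at least 2.83-fold lower (list median -0.82, adjusted p = 0.000381, p(est) = 0.289). Of 19 B lymphoid genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), including Dntt (-3.78) and Il7r (-2.02), with a median of -0.72 (adjusted p = 0.00781, p(est) = 0.506). Of 18 stromal and endothelial genes 7 fell and 2 rose (7 and 2 adjusted over the list alone), with the chemokine gene Cxcl12 lower (-4.17, but a raised fold of 7.67, as 5 of the 6 BCR-ABL arrays lay at background) and Igfbp7 higher (2.54). Of 11 plasmacytoid dendritic genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), including Siglech (-2.70, with 2 arrays at background, raised fold 5.22). The medians of these lists were -0.48 (adjusted p = 0.0358) and -0.90 (adjusted p = 0.01), with a p(est) = 0.289 for each. The stromal call was lost with raised values (adjusted p = 0.053) and without neither replicate 2 or 4 or BCR-ABL replicate 2 or 4 (highest adjusted p = 0.061). MHC class II genes fell in 7 of 9 cases (7 adjusted over the list alone), with their transactivator Ciita at -2.16 and H2-Eb1 at -1.55 (list median -0.67, adjusted p = 0.000121, p(est) = 0.289). Of 19 interferon response genes 11 fell (13 adjusted over the list alone). They included the antiviral genes Mx1 (-1.42) and Oas2 (-1.03) and the transcription factor Irf7 (-0.85), with a median of -0.62 (adjusted p = 5.32e-06, p(est) = 0.289).

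Of 18 p53 targets 11 rose with BCR-ABL and 0 fell (12 adjusted over the list alone). They included Phlda3 (2.88), Eda2r (2.79) and the death receptor gene Tnfrsf10b (1.01), with 2, 5 and 1 arrays of neither at background (raised folds 7.16, 3.55 and 2.01), and the median was 0.45 (adjusted p = 4.25e-05, p(est) = 0.289). Of 22 genes of ribosome biogenesis and MYC targets 21 rose (21 adjusted over the list alone, and 1 fell). The changes were small, such as 0.63 for Polr1b, a subunit of RNA polymerase I, and 0.49 for Cad. Rrs1 had a change of -0.12 (adjusted p = 0.0712, but 0.0258 with raised values; list median 0.26, adjusted p = 7.88e-09, p(est) = 0.289). Of 17 cholesterol synthesis genes 5 rose (5 adjusted over the list alone), led by Lss (1.11) and Idi1 (0.76), with a median of 0.18 (adjusted p = 0.00373, p(est) = 0.404). No call was made for cell cycle genes, of which 0 of 31 rose and 4 fell (1 adjusted over the list alone; median -0.07, adjusted p = 0.0502, but 0.0248 with raised values). Nor was one made for the BCL2 family (3 of 14 up and 3 down, 3 and 3 adjusted over the list alone; Bcl2l11 -0.83, Bcl2 0.72; adjusted p = 0.821) and Wnt, Notch and Musashi-Numb genes (4 of 17 up and 3 down, 4 and 4 adjusted over the list alone; adjusted p = 0.904). The same held for glycolysis and hypoxia (4 of 21 up and 1 down, 4 and 1 adjusted over the list alone; 0.304), oxidative phosphorylation (1 of 22 up and 1 down, 0 and 0 adjusted over the list alone; 0.0621, but 0.0444 with raised values) and immediate early genes (1 of 18 down, Gadd45b at -0.67, 1 adjusted over the list alone; 0.0686). All 6 BCR-ABL arrays lay on the called side of the mean in neither for 108 of the 111 named calls. The share of called genes that rose was 50.29%, and 67.61% after scaling to a common median.

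NUP98-HOXA9 was compared with neither in the same way. Members of the HOXA9 and MEIS1 list rose and members of the T and NK list fell, and these list calls held with an estimated correlation. Of 18193 genes, 665 rose and 397 fell, 399 of them at least 2-fold. Hoxb6 rose by 2.99 (SE 0.22, adjusted p = 1.04e-07), Meis1 by 0.79 (SE 0.11, adjusted p = 0.000115) and Msi2 by 0.49 (SE 0.10, adjusted p = 0.00365). Kit and Cd34 had changes of 0.14 and 0.24 (adjusted p = 0.57 and 0.371), Numb of -0.24 (adjusted p = 0.659) and Bcr of 0.17 (adjusted p = 0.223). Other large rises were those of the ephrin receptor gene Epha3 (3.66, SE 0.69, adjusted p = 0.00181) and the glutathione transferase gene Gsta3 (3.14, SE 0.40, adjusted p = 3.71e-05). So were those of the transporter genes Slc16a12 (3.14, adjusted p = 0.00267) and Slc13a5 (2.74, adjusted p = 0.000762), and Rims2 (2.83, SE 0.36, adjusted p = 3.71e-05), and Fxyd4 was at least 3.34-fold higher (adjusted p = 0.00708). In neither, 5, 2, 3, 3 and 1 arrays lay at background for Epha3, Gsta3, Slc16a12, Slc13a5 and Rims2 (raised folds 3.36, 7.07, 8.11, 6.17 and 6.76), and Fxyd4 did not pass with raised values (adjusted p = 0.127). Among the largest falls were those of Gzma (-4.85, SE 0.42, adjusted p = 4.01e-07), Cd3e (-4.84, SE 0.59, adjusted p = 2.19e-05) and Cxcr6 (-4.51, adjusted p = 0.000736), where 5 NUP98-HOXA9 arrays lay at background for each of Cd3e and Cxcr6 (raised folds 15.5 and 8.4). Klrc1 and Cyp1b1 were at least 13.6-fold and 5.19-fold lower (adjusted p = 4.35e-07 and 2.33e-06), and the immunoglobulin segments Igk-V21 and Igkv6-15 were at least 11.6-fold and 10.5-fold lower (adjusted p = 0.00092 and 0.000415).

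Of the HOXA9 and MEIS1 programme 8 of 21 genes rose with NUP98-HOXA9 and 1 fell (12 and 2 adjusted over the list alone). Mycn was at 1.85, Hoxa5 at 1.14, Hoxa10 at 0.92 and Camk2d at -0.99. Myb had a change of 0.07. This list was higher (median 0.29, adjusted p = 3.23e-07) and held with an estimated correlation (adjusted p = 0.00181). Of the stem and progenitor markers 7 of 21 rose (7 and 1 adjusted over the list alone), including Mllt3 (1.18) and Angpt1 (1.07), with a median of 0.13 (adjusted p = 0.000327, p(est) = 0.203). T and NK genes fell in 12 of 17 cases and rose in 1 (13 and 1 adjusted over the list alone). The transcription factor gene Gata3 was at least 2.01-fold (but adjusted p = 0.164 with raised values) and Ncr1 at least 2.83-fold lower, while the perforin gene Prf1 had a change of 0.03. The list median was -2.79, or -1.53 with raised values (adjusted p = 1.14e-16). The call held with an estimated correlation (adjusted p = 0.0116). Of 19 B lymphoid genes 7 fell (14 adjusted over the list alone). The transcription factor Ebf1 was at -3.25, the recombinase gene Rag1 at -3.17, Dntt at -3.12 and Pou2af1 at -2.71, and Cd79b had a change of -0.50 (adjusted p = 0.262). Their list median was -2.13 (adjusted p = 5.14e-11, p(est) = 0.143). The 4 named B calls were lost when single arrays were left out. For Ebf1 this was any of 16 (adjusted p = 0.116 without NUP98-HOXA9 replicate 1), for Dntt any of 9 (0.0878 without neither replicate 6). For Rag1 and Pou2af1 it was any of 6 (0.0865 and 0.0724 without NUP98-HOXA9 replicate 4). Ebf1 and Rag1 had 2 and 1 arrays at background (raised folds 9.21 and 8.97), and Ebf1 did not pass with raised values (adjusted p = 0.0547).

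Stromal genes fell in 5 of 18 cases with NUP98-HOXA9 and rose in 1 (8 and 1 adjusted over the list alone). Cxcl12 was at least 7.94-fold lower, Bgn at -2.93 (2 arrays at background, raised fold 6.61) and Igfbp7 at 2.07. The median was -0.64, or -0.26 with raised values (adjusted p = 0.001, p(est) = 0.143). Of 19 monocyte markers 2 fell, Cd209a (-1.63, with 1 array at background, raised fold 2.93) and the Fc receptor gene Fcgr1 (-0.79). Adjusted over the list alone, 4 fell (median -0.25, adjusted p = 0.000379, p(est) = 0.665). The calls of these 2 genes ended without NUP98-HOXA9 replicate 2, at adjusted p = 0.0895 and 0.091. Of 31 cell cycle genes 2 fell, the cyclins Ccne1 (-0.35) and Ccne2 (-0.25), also adjusted over the list alone, with a median of -0.12 (adjusted p = 8.67e-07, p(est) = 0.302). Wnt and Notch genes fell in 3 of 17 cases and rose in 1 (5 and 1 adjusted over the list alone), with Lef1 at -2.73 and Jag1 at -1.40 (median -0.13, adjusted p = 0.00401, p(est) = 0.0881). Of 22 ribosome biogenesis genes 0 passed on their own (median 0.09, adjusted p = 0.0027, p(est) = 0.665). The other 16 lists were not called (adjusted p from 0.0656 to 0.821), among them erythroid (adjusted p = 0.821) and megakaryocyte genes (0.207), but oxidative phosphorylation passed with raised values (0.028). In all 9 lists were called, 3 higher and 6 lower, and all 6 arrays lay on the called side for each of the 54 named calls.

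The changes of the single oncogenes against neither were set beside each other. With each of them 376 genes rose, against 90.25 that independent lists would share. With each of them 239 fell, against 53.27. Across 18193 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.522 and Spearman's rho = 0.461. These comparisons share the 6 control arrays: unchanged groups simulated against them gave a mean r of 0.498 (from 0.47 to 0.522 in 100 simulations) and a mean rho of 0.446. The covariance was 0.173 against 0.0445 simulated, a difference of 0.128. With the control arrays split into 3 and 3, over 20 assignments, r averaged 0.354 (from 0.246 to 0.451), and 178 genes rose and 112 fell in common against 38.3 and 20.6 for independent lists.

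Cells with both oncogenes were compared with neither to describe the combined state. Members of the megakaryocyte, p53 and RAS-ERK lists rose and members of the neutrophil, monocyte, interferon and lymphoid lists fell. None of them held with an estimated correlation. Of 18193 genes 1912 rose and 1894 fell, 1282 of them at least 2-fold. The largest rises were those of Psg17 (6.25, SE 1.13, adjusted p = 0.000363), Crisp3 (6.02, SE 0.98, adjusted p = 0.000125), the milk casein genes Csn1s2b (5.95, SE 1.25, adjusted p = 0.00149) and Csn1s2a (5.50, SE 1.16, adjusted p = 0.0015), and Gdf10 (5.17, SE 0.61, adjusted p = 3.48e-06). For these genes 4, 5, 3, 3 and 4 arrays of neither lay at background (raised folds 28.3, 27, 33.1, 35.1 and 17.7). The endogenous retroviral gene Erv3 was at least 20-fold (adjusted p = 0.000201) and Mcpt1 at least 9.89-fold higher (adjusted p = 4.55e-06). Among the largest falls were those of Igk-V21 (-5.07, adjusted p = 0.00018), the immunoglobulin heavy chain gene Igha (-4.97, adjusted p = 8.83e-05) and Cyp7b1 (-4.83, SE 0.50, adjusted p = 8.65e-07), with 5, 1 and 5 arrays of both at background (raised folds 10.9, 31 and 10). Klrc1, Igkv6-15, Cxcr6 and Cd209a were at least 13.6-, 10.5-, 8.69- and 5.05-fold lower (adjusted p = 2.23e-08, 3.90e-06, 5.23e-05 and 2.17e-07). Meis1 rose by 0.90 (adjusted p = 6.03e-06) and Msi2 by 0.73 (adjusted p = 2.33e-05), and Kit and Cd34 fell by 0.88 (adjusted p = 7.22e-06) and by 0.44 (adjusted p = 0.0205). The Cd34 call was lost without 2 of the arrays (highest adjusted p = 0.0613, without both replicate 6). Numb, Bcr and Nup98 had changes of -0.52, -0.08 and -0.02 (adjusted p = 0.11, 0.541 and 0.868).

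With both oncogenes, 11 of 16 megakaryocyte genes rose (12 adjusted over the list alone). Among them were Ppbp (2.79), Gp1bb (2.45) and Pf4 (2.02), and the median was 1.42 (adjusted p = 1.86e-07, p(est) = 0.261). Of 21 erythroid genes 7 rose (7 adjusted over the list alone), with Rhag at 2.00 and Epor at 1.37 (median 0.40, adjusted p = 0.0116, p(est) = 0.491). These gene calls were lost without neither replicate 1, among others (adjusted p = 0.0664 and 0.057). Stem and progenitor markers had 8 of 21 up and 4 down (9 and 4 adjusted over the list alone). Slamf1 was at 2.15 and Mycn at 1.95 (list median 0.47, or 0.24 with raised values; adjusted p = 0.0138, but 0.0553 without both replicate 1, p(est) = 0.308). STAT5 targets had 8 of 17 up and 2 down (8 and 3 adjusted over the list alone), with Il2ra at 3.68, Socs2 at 1.84 and Bcl6 at -1.43 (median 0.16, or 0.10 raised; adjusted p = 0.0127, p(est) = 0.261). RAS-ERK targets had 8 of 17 up and 1 down (9 and 2 adjusted over the list alone), with Spry4 at 2.61 and the transcription factor Fosl1 at 2.24 (median 0.40, adjusted p = 0.000999, p(est) = 0.261). Of 18 p53 targets 10 rose (12 adjusted over the list alone), with Phlda3 at 2.00 and Zmat3 at 1.72 (median 0.36, adjusted p = 1.40e-05, p(est) = 0.261). Of 22 ribosome biogenesis genes 11 rose (18 adjusted over the list alone), with Polr1b at 0.43 (median 0.18, adjusted p = 8.04e-07, p(est) = 0.261). Of 17 cholesterol synthesis genes 5 rose (5 adjusted over the list alone), with Lss at 1.02 (median 0.16, adjusted p = 0.00608, p(est) = 0.432). In neither, 1, 3 and 2 arrays lay at background for Spry4, Fosl1 and Phlda3 (raised folds 5.89, 3.84 and 3.91).

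Among the lists that were lower with both, 10 of 17 late neutrophil genes fell (11 adjusted over the list alone), with Mmp9 at -3.36 and the granule protein gene Ltf at -1.30 (median -0.61, adjusted p = 4.77e-05, p(est) = 0.308). Of 19 monocyte markers 7 fell (8 adjusted over the list alone), with Irf8 and F13a1 at -1.94 each (median -0.50, adjusted p = 2.46e-05, p(est) = 0.308). Of 13 early granulocyte genes 5 fell (6 adjusted over the list alone), with Fcnb at -0.80 (median -0.11, and 0.019 only with a common median, which moved all genes alike; adjusted p = 0.0138, p(est) = 0.473). Of 19 interferon genes 10 fell (12 adjusted over the list alone), with Oas2 at -1.19 and Usp18 at -1.14 (median -0.65, adjusted p = 8.04e-07, p(est) = 0.261). Of 9 MHC class II genes 7 fell (7 and 1 up adjusted over the list alone), with Ciita at -1.76 (median -0.56, adjusted p = 0.00031, p(est) = 0.261). B lymphoid genes fell in 10 of 19 cases (10 adjusted over the list alone), with Dntt at -4.81 and Rag1 at -3.02 (median -1.73, adjusted p = 5.97e-06, p(est) = 0.261). T and NK genes fell in 8 of 17 and rose in 1 (8 and 1 adjusted over the list alone). Gzma was at -4.56, Cd3e at -4.24 and Cd3d at least 8.45-fold lower (list median -1.57, or -0.98 with raised values; adjusted p = 1.40e-05, p(est) = 0.261). Plasmacytoid dendritic genes fell in 4 of 11 (5 and 1 up adjusted over the list alone), with Siglech at -2.86 (median -0.45, adjusted p = 0.0132, p(est) = 0.292). Stromal genes fell in 9 of 18 and rose in 1 (10 and 2 adjusted over the list alone). Cxcl12 was at least 7.94-fold lower, Bgn at -3.32 and Igfbp7 at 3.29 (list median -0.66, or -0.29 with raised values; adjusted p = 0.021, but 0.0557 raised, p(est) = 0.261). The cell cycle list was also lower, with 1 of 31 members past the threshold, E2f1 at -0.39 (1 adjusted over the list alone). Its median was -0.07, and 0.058 only with that common shift (adjusted p = 0.0197, p(est) = 0.505). This call was lost without both replicate 4 or 5 (0.0801 at most). In both, 1, 1, 3, 4 and 3 arrays lay at background for Dntt, Rag1, Cd3e, Siglech and Bgn (raised folds 24.6, 7.84, 16.6, 5.48 and 7.5).

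The HOXA9 and MEIS1 programme was not called with both against neither (7 of 21 up and 4 down, 8 and 4 adjusted over the list alone; adjusted p = 0.0726), nor were 6 other lists (adjusted p from 0.075 to 0.435). In all 18 lists were called, 8 higher and 10 lower. The share of called genes that rose was 50.24%, and 60.79% after quantile normalization, 77.83% with a common median and 61.6% with a common 75th percentile. A common median moved the median of all genes by 0.132.

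Cells with both oncogenes were compared with BCR-ABL cells to ask what NUP98-HOXA9 added to BCR-ABL. Few genes passed: 20 rose and 3 fell of 18193, of which 7 changed at least 2-fold, and 1496 had an unadjusted p under 0.05. A fit of only these 12 arrays called 1 gene, and a fit of all arrays with the replicate number as a fixed block called 158. The named rises were those of Skap1, a T cell adaptor gene (1.69, SE 0.24, adjusted p = 0.0037), the potassium channel gene Kcnq3 (1.47, SE 0.29, adjusted p = 0.0358, 1 array at background, raised fold 2.58), Neto2 (1.08, SE 0.20, adjusted p = 0.0343), Ttc12 (1.05, adjusted p = 0.0343) and the germ cell helicase gene Ddx4 (0.82, SE 0.15, adjusted p = 0.0343). Nccrp1 and Fgf14 were at least 1.53-fold and 1.25-fold higher (adjusted p = 0.0343 and 0.0363). Ildr2 (-2.46, SE 0.49, adjusted p = 0.0397), the collagen gene Col16a1 (-0.80, adjusted p = 0.0343, 1 array at background, raised fold 1.74) and Abhd16a (-0.37, adjusted p = 0.0343) fell. Of these 10 calls only that of Skap1 held without each of the 24 arrays, and that of Ildr2, with 5 arrays of both at background (raised fold 2.89), was lost without any of 19 (highest adjusted p = 0.126, without both replicate 5). The others were lost without 6 to 13 arrays, for example without both replicate 3 (Neto2, Ddx4, Nccrp1 and Col16a1, each with adjusted p = 0.0974). With raised values Nccrp1, Fgf14 and Ildr2 did not pass (adjusted p = 0.174, 0.343 and 0.158). Hoxa9 had a change of 0.17 (adjusted p = 0.696), and its second probe set one of 0.70 (adjusted p = 0.101). For each probe set all 6 arrays of both lay above all 6 of BCR-ABL (12.06 to 12.18 against 11.83 to 12.04 in the first), for which an exact permutation test gave p = 0.00216, the smallest it can give. Meis1, Msi2, Kit, Cd34, Numb, Nup98, Bcr and Abl1 had changes of -0.21, -0.11, -0.13, 0.25, 0.09, -0.05, 0.10 and -0.20 (adjusted p between 0.485 and 0.973).

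No member of any list passed the threshold in both against BCR-ABL by limma. Camera called 7 lists, 4 higher and 3 lower, and fry 0. The early granulocyte (median 0.11, adjusted p = 0.0009), monocyte (0.19, adjusted p = 0.049), mast cell (0.24, or 0.11 with raised values; adjusted p = 0.0439, but 0.0545 raised) and BCL2 family lists (0.11, adjusted p = 0.0149) were higher. The erythroid (-0.41, adjusted p = 7.26e-05), B lymphoid (-0.64, adjusted p = 0.0009) and ribosome biogenesis lists (-0.07, adjusted p = 0.00101) were lower. All were lost with an estimated correlation, where the adjusted p was 0.928 for monocyte, 0.927 for mast cell, 0.478 for the BCL2 family and 0.724 for the other called lists. The monocyte call was lost without any of 14 arrays (highest adjusted p = 0.656) and the mast cell call without any of 8 (0.326). The B call was lost without BCR-ABL replicate 6 (0.0574), and the BCL2 call was lost without BCR-ABL replicate 6 or both replicate 4 (0.0635 at most). Adjusted over the list alone, 3 stem cell markers, 1 megakaryocyte, 1 cholesterol and 2 glycolysis genes fell, and 1 early granulocyte, 1 mast cell and 1 glycolysis gene rose. The count of changed genes was 56 without BCR-ABL replicate 3 and 3 without both replicate 5.

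Cells with both were compared with NUP98-HOXA9 cells to ask what BCR-ABL added. Of 18193 genes 987 rose and 1384 fell, 740 of them at least 2-fold. Members of the RAS-ERK, megakaryocyte and p53 lists rose, and members of the MHC class II and interferon lists fell, but none of these list calls held with an estimated correlation. Gdf10 rose by 5.45 (SE 0.61, adjusted p = 5.77e-06), the T cell receptor gamma segment Trgv1 by 4.24 (SE 0.90, adjusted p = 0.00303), the serine protease gene Htra3 by 4.12 (SE 0.30, adjusted p = 2.37e-08) and Erc2 by 3.75 (adjusted p = 0.000321), and Sardh was at least 2.27-fold higher (adjusted p = 0.0008, but 0.087 with raised values). Serpinb9g and Psg17 rose by 4.20 and 3.80 (adjusted p = 0.0244 and 0.0287), calls that were lost without both replicate 3 (0.0595) and without NUP98-HOXA9 replicate 1 (0.0773) among others. In NUP98-HOXA9, 5, 2, 2, 5, 5 and 3 arrays lay at background for Gdf10, Trgv1, Htra3, Erc2, Serpinb9g and Psg17 (raised folds 18.1, 14.7, 16.6, 6.56, 7.63 and 8.34). Hnmt (-3.57, SE 0.26, adjusted p = 1.79e-08), Fcer1a (-3.23, SE 0.34, adjusted p = 3.88e-06), Slc13a5 (-3.20, adjusted p = 0.000127, 2 arrays at background, raised fold 7.72) and Gpc4 (-3.15, SE 0.36, adjusted p = 8.86e-06) fell. Plg, Foxd4 and Cd209a were at least 5.08-, 6.01- and 1.63-fold lower (adjusted p = 2.45e-07, 0.000165 and 6.99e-05). Kit fell by 1.03 (adjusted p = 4.29e-06), Cd34 by 0.68 (adjusted p = 0.0015) and Bcr by 0.25 (adjusted p = 0.0323, and 0.0728 without both replicate 4). Hoxa9, Meis1, Msi2, Numb, Nup98 and Abl1 had changes of -0.22, 0.11, 0.23, -0.28, -0.01 and -0.13 (adjusted p from 0.14 to 0.916).

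Of 16 megakaryocyte genes 9 rose in this comparison (10 adjusted over the list alone), with Gp1bb at 2.35 and Treml1 at 2.19 (median 0.86, adjusted p = 2.18e-07, p(est) = 0.328). Of 17 RAS-ERK targets 10 rose and 2 fell (10 and 2 adjusted over the list alone), with Spry4 at 2.18 and Phlda1 at 1.39 (median 0.39, adjusted p = 0.00068, p(est) = 0.328). Of 18 p53 targets 7 rose (8 adjusted over the list alone), with Phlda3 at 2.48 and Zmat3 at 1.58 (median 0.25, adjusted p = 5.98e-05, p(est) = 0.328). Of 17 cholesterol synthesis genes 7 rose (8 adjusted over the list alone), with Lss at 0.80 (median 0.29, adjusted p = 1.59e-05, p(est) = 0.335). Erythroid genes rose in 2 of 21 cases (2 adjusted over the list alone), Epor at 1.55 and Car2 at 0.99 (median 0.55, adjusted p = 0.000879, p(est) = 0.466). T and NK genes rose in 5 of 17 and fell in 1 (6 and 1 adjusted over the list alone), with the T cell transcription factor Bcl11b at 2.68 (adjusted p = 0.0864 with raised values) and Klrd1 at -1.93. Their median was 0.37, or 0.05 with raised values (adjusted p = 0.0315, but 0.147 raised and 0.0576 at most without NUP98-HOXA9 replicate 4 or both replicate 3, p(est) = 0.467). Ribosome biogenesis and oxidative phosphorylation were higher with 0 of 22 members past the threshold in each (medians 0.09 and 0.05, adjusted p = 0.00068 and 0.00665, p(est) = 0.419 and 0.467). STAT5 targets had 8 of 17 up and 2 down (8 and 2 adjusted over the list alone), with Il2ra at 2.33 (lost without 3 arrays, adjusted p = 0.0613 without NUP98-HOXA9 replicate 5) and Socs2 at 1.65. Their test was higher (adjusted p = 0.047, but 0.0665 with raised values and 0.0779 at most without any of 12 arrays, p(est) = 0.419) while their median was -0.05, and positive only with a common median or 75th percentile (0.063 and 0.016), which moved all genes alike. In NUP98-HOXA9, 2, 1, 5 and 3 arrays lay at background for Spry4, Treml1, Bcl11b and Phlda3 (raised folds 4.25, 4.45, 2.81 and 3.59).

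Interferon genes fell in 7 of 19 cases (10 adjusted over the list alone), with Oas2 at -1.41 and Mx1 at -0.93 (median -0.47, adjusted p = 1.39e-06, p(est) = 0.328). MHC class II genes fell in 3 of 9 (5 adjusted over the list alone), with H2-Ob at -0.88 (median -0.53, adjusted p = 0.000879, p(est) = 0.356). Late neutrophil genes fell in 5 of 17 (7 and 1 up adjusted over the list alone), with Mmp9 at -2.72 and the receptor gene Csf3r at -0.95 (median -0.47, adjusted p = 0.000879, p(est) = 0.466). Early granulocyte genes fell in 6 of 13 (7 adjusted over the list alone), with Fcnb at -0.65 (median -0.11, and 0.007 only with a common median; adjusted p = 0.00209, p(est) = 0.466). Monocyte markers fell in 4 of 19 (4 adjusted over the list alone), with F13a1 at -1.80 and Irf8 at -1.57 (median -0.16, adjusted p = 0.0315, but 0.0665 with raised values and 0.118 at most without NUP98-HOXA9 replicate 4 or 5 or both replicate 2, p(est) = 0.654). Plasmacytoid dendritic genes fell in 3 of 11 (4 adjusted over the list alone), with Siglech at -2.35 and 4 arrays of both at background (raised fold 3.85; median -0.32, adjusted p = 0.0315, and 0.0824 at most without NUP98-HOXA9 replicate 1 or 6 or both replicate 3 or 4, p(est) = 0.419). The HOXA9 and MEIS1 programme had 6 of 21 down and 2 up (7 and 3 adjusted over the list alone), with Cd28 at -1.37 and Igf1 at 2.24 (median -0.13, adjusted p = 0.0491, but 0.0549 raised and 0.0815 at most without any of 15 arrays, p(est) = 0.328). The other lists were not called (adjusted p from 0.0689 to 0.893). The share of called genes that rose was 41.63%, and 56.95% after quantile normalization, 73.26% with a common median and 59.69% with a common 75th percentile, where a common median moved the median of all genes by 0.108. Without NUP98-HOXA9 replicate 2, a count chosen after the values were seen, 3035 genes changed.

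BCR-ABL and NUP98-HOXA9 cells were also compared directly. Of 18193 genes 1616 were higher and 1993 lower in BCR-ABL, 1076 of them by at least 2-fold. Gdf10 (5.87, SE 0.61, adjusted p = 9.10e-07), Trgv1 (5.19, SE 0.90, adjusted p = 0.000301), the oxytocin receptor gene Oxtr (4.24, SE 0.62, adjusted p = 5.18e-05), Slamf1 (4.13, SE 0.49, adjusted p = 5.23e-06) and Mcpt1 (4.00, SE 0.63, adjusted p = 0.000111) were higher in BCR-ABL. In NUP98-HOXA9, 5, 2, 2, 1 and 4 arrays lay at background for these genes (raised folds 24.3, 28.4, 16.1, 15.5 and 10.3). Also higher were Dmd, at least 7.87-fold (adjusted p = 2.66e-07), and Gata3, at least 1.78-fold (adjusted p = 0.000246, but 0.123 with raised values). The growth factor gene Nrg1 (-3.63, SE 0.45, adjusted p = 8.51e-06), Slc13a5 (-3.61, adjusted p = 1.42e-05), Gpc4 (-3.61, SE 0.36, adjusted p = 6.07e-07) and the ephrin receptor gene Epha7 (-3.61, SE 0.34, adjusted p = 2.88e-07) were lower, as was Upb1 (-3.43, SE 0.29, adjusted p = 7.04e-08). For Nrg1, Slc13a5 and Epha7 3, 4 and 1 BCR-ABL arrays lay at background (raised folds 8.86, 8.94 and 10.6). Plg and Efcab3 were at least 5.08-fold and 4.89-fold lower (adjusted p = 4.08e-08 and 2.64e-06). Kit (-0.89, adjusted p = 8.47e-06), Cd34 (-0.93, adjusted p = 3.77e-05), Bcr (-0.35, adjusted p = 0.00258) and Hoxa9 (-0.39, adjusted p = 0.00495) were lower in BCR-ABL. Meis1 (0.32, adjusted p = 0.0425) and Msi2 (0.35, adjusted p = 0.0188) were higher. These calls were lost without any of 8 arrays for Meis1 (0.11 without NUP98-HOXA9 replicate 3) and without BCR-ABL replicate 6 for Msi2 (0.0523). Numb, Nup98 and Abl1 differed by -0.38, 0.04 and 0.07 (adjusted p = 0.277, 0.65 and 0.6).

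Erythroid genes were higher in BCR-ABL in 11 of 21 cases (13 adjusted over the list alone), with Epor at 2.46 and Ank1 at 1.91 (median 1.10, adjusted p = 2.03e-06, p(est) = 0.241). Megakaryocyte genes were higher in 8 of 16 (10 adjusted over the list alone), with Gp1bb at 2.67 and the von Willebrand factor gene Vwf at 2.48 (median 0.87, adjusted p = 2.51e-06, p(est) = 0.241). RAS-ERK targets had 10 of 17 higher and 1 lower (10 and 1 adjusted over the list alone), with Spry4 at 2.27 (median 0.44, adjusted p = 0.000452, p(est) = 0.241). The p53 targets had 8 of 18 higher (9 adjusted over the list alone), with Phlda3 at 3.35 (median 0.27, adjusted p = 0.00041, p(est) = 0.241). Ribosome biogenesis had 8 of 22 (14 adjusted over the list alone), with Cad at 0.40 (median 0.16, adjusted p = 2.51e-06, p(est) = 0.241), and cholesterol synthesis had 6 of 17 (7 adjusted over the list alone), with Idi1 and Lss at 0.88 (median 0.22, adjusted p = 2.15e-05, p(est) = 0.241). Wnt and Notch genes had 6 of 17 higher and 1 lower (6 and 1 adjusted over the list alone), with Lef1 at 2.89 (median 0.35, or 0.12 with raised values; adjusted p = 0.0148, p(est) = 0.241). T and NK genes had 7 of 17 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.69, or 0.27 raised; adjusted p = 0.00931, but 0.0777 raised, p(est) = 0.389). B genes had 1 of 19 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.59, adjusted p = 0.0452, and 0.181 at most without any of 6 arrays, p(est) = 0.654). Oxidative phosphorylation had 3 of 22 higher (2 adjusted over the list alone), with Ndufs1 at 0.27 (median 0.08, adjusted p = 0.000723, p(est) = 0.389). Lower in BCR-ABL were early granulocyte genes (9 of 13, also adjusted over the list alone; Gfi1 -0.87, Cebpa -0.74; median -0.22, adjusted p = 2.15e-05, p(est) = 0.241) and interferon genes (9 of 19, 10 adjusted over the list alone; median -0.49, adjusted p = 1.56e-05, p(est) = 0.241). The same held for MHC class II genes (5 of 9, 6 adjusted over the list alone; median -0.66, adjusted p = 0.00041, p(est) = 0.241) and monocyte markers (5 of 19, 6 adjusted over the list alone; Irf8 -1.74; median -0.38, adjusted p = 0.00135, p(est) = 0.5). So were late neutrophil genes (3 of 17 lower and 1 higher, also adjusted over the list alone; Mmp9 -2.57; median -0.37, adjusted p = 0.0105, and 0.0506 without BCR-ABL replicate 2, p(est) = 0.57) and the HOXA9 and MEIS1 programme (7 of 21 lower and 4 higher, 9 and 5 adjusted over the list alone; Cd28 -2.18, Igf1 2.05; median -0.25, adjusted p = 0.0148, p(est) = 0.241). Plasmacytoid dendritic genes were lower too (3 of 11 lower and 1 higher, 4 and 1 adjusted over the list alone; Siglech -2.19; median -0.48, adjusted p = 0.033, and 0.0833 at most without BCR-ABL replicate 5 or NUP98-HOXA9 replicate 1 or 6, p(est) = 0.389). In the lower group, 2, 2, 3 and 2 arrays lay at background for Spry4, Ank1, Phlda3 and Siglech (raised folds 4.53, 3.67, 6.58 and 3.66).

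The other lists were not called in BCR-ABL against NUP98-HOXA9 (adjusted p from 0.138 to 0.779). The share of called genes that were higher in BCR-ABL was 44.78%, and 54.97% after quantile normalization, 61.32% with a common median and 56.5% with a common 75th percentile.

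**Figure D3:**
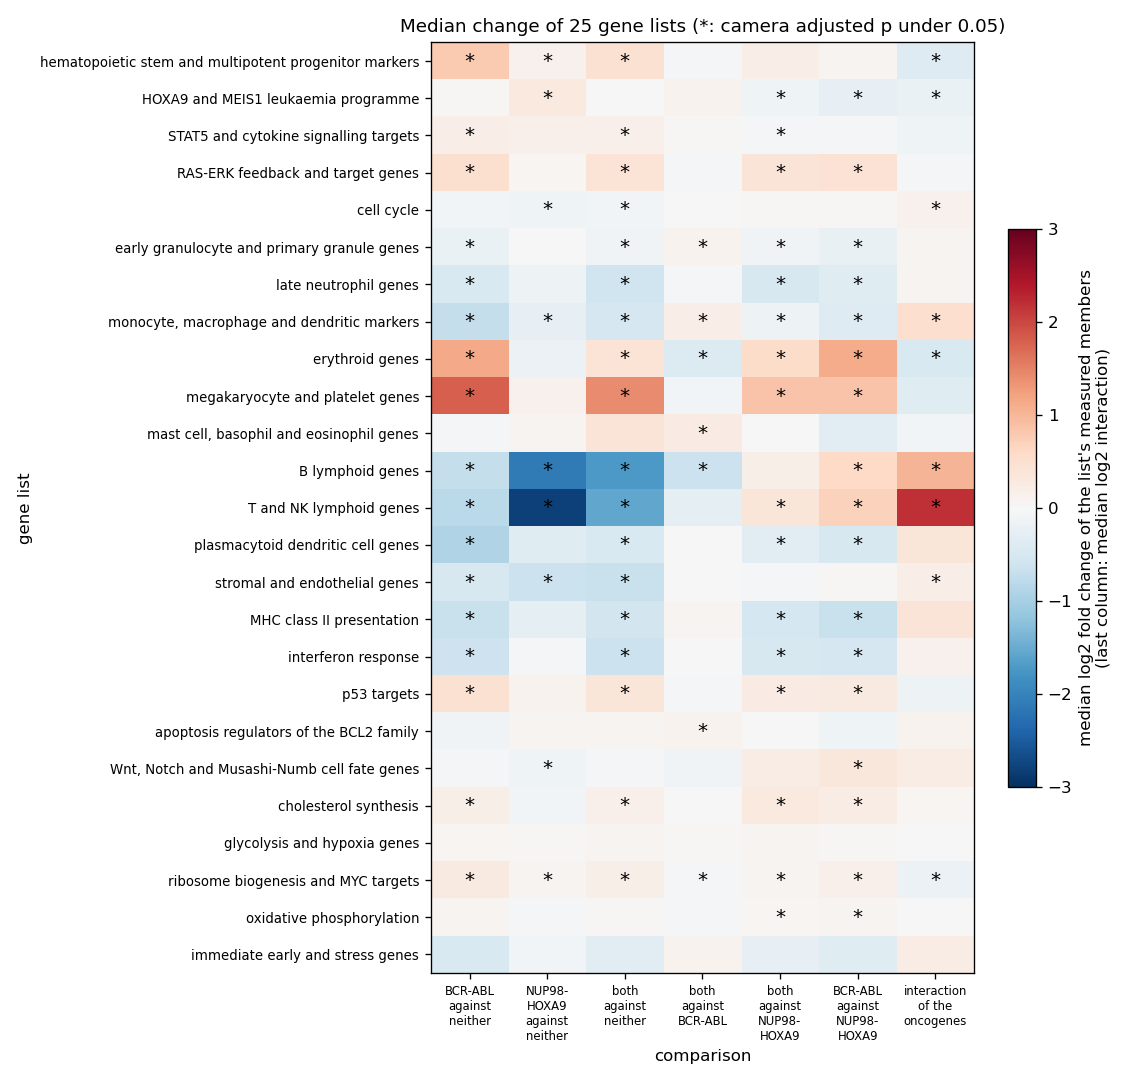
Median log2 fold change (colour, from -3 to 3) of the measured members of 25 gene lists (y axis) in the 6 comparisons of 2 groups and the median log2 interaction (x axis), with an asterisk where camera gave an adjusted p under 0.05. Megakaryocyte genes had medians of 1.79 with BCR-ABL and 1.42 with both against neither, and T and NK genes had a median of -2.79 with NUP98-HOXA9 against neither.

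The interaction asked whether the effect of 1 oncogene differed in the presence of the other. It was past the threshold for 199 of 18193 genes, positive in 59 and negative in 140, and 109 were at least 2-fold. With the replicate number as a fixed block the count was 1083. Meis1 had an interaction of -0.999 (SE 0.16, adjusted p = 0.00272), with mean levels of 9.24 in neither, 10.35 in BCR-ABL, 10.02 in NUP98-HOXA9 and 10.14 in both. Hoxb6 had one of -2.64 (SE 0.31, adjusted p = 0.000266) with levels of 5.79, 8.46, 8.78 and 8.81, and Hoxc5 one of -1.94 (SE 0.35, adjusted p = 0.00829) with levels of 7.08, 9.66, 9.44 and 10.08. Msi2 had a value of -0.60 (SE 0.14, adjusted p = 0.0434), lost without any of 16 arrays (0.0853 without both replicate 3). Hoxa9, Kit, Cd34, Numb, Bcr, Abl1 and Nup98 had values of -0.42, -0.28, 0.01, 0.34, -0.08, -0.04 and -0.05 (adjusted p from 0.123 to 0.985). Other negative values were those of Ildr2 (-3.06, adjusted p = 0.035, and 0.07 without both replicate 5 and 0.206 with raised values), Gsta3 (-2.75, adjusted p = 0.0212), Mab21l2 (-2.23, adjusted p = 0.00271) and Rab40b (-2.12, adjusted p = 0.00623), with Lypd6b, Dsp, Icam4 and Nefh from -1.88 to -1.72 (adjusted p from 0.0158 to 0.0212).

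The largest positive interactions were those of Cd3e (5.38, SE 0.83, adjusted p = 0.00272), Cxcl12 (4.81, SE 0.84, adjusted p = 0.0066), Cyp1b1 (4.76, SE 0.66, adjusted p = 0.00162), Mmp13 (4.19, SE 0.61, adjusted p = 0.00191) and Igkv14-111 (4.17, adjusted p = 0.0254, and 0.0515 without both replicate 3). Next were the T cell receptor segment Trbv1, Klrc1, Gzma, the NK receptor gene Klrb1a and Ncr1, from 3.74 to 4.17 (adjusted p from 0.00162 to 0.012). Of these 59 genes 45 were highest in neither and fell with each oncogene alone, and 18 had means at or under the background in each of the 3 groups with an oncogene. Among these were Cd3e, Cxcl12, Cyp1b1, Mmp13 and Klrc1, so that the sizes and order of their values are uncertain. With raised values they had interactions of 3.82, 2.94, 2.38, 2.88 and 3.77, Igkv14-111, Trbv1 and Klrb1a had 3.95, 3.53 and 2.71, and Ncr1 did not pass (1.53, adjusted p = 0.199). The T and NK list was called (4 of 17 positive, 13 and 1 negative adjusted over the list alone; median 2.19, or 1.53 with raised values; adjusted p = 8.69e-12) and held with an estimated correlation (adjusted p = 0.0491). So was the B list (1 of 19 positive, also adjusted over the list alone; median 1.03, adjusted p = 0.000577, p(est) = 0.535). The stromal list was positive too (1 of 18 positive, 5 and 1 negative adjusted over the list alone; median 0.20, adjusted p = 0.00345, p(est) = 0.241). Monocyte and cell cycle lists were positive with 0 of 19 and 0 of 31 members past the threshold (medians 0.51 and 0.12, adjusted p = 1.38e-05 and 0.000105, p(est) = 0.494 for both).

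Negative interactions were called for stem and progenitor markers (5 of 21 negative, 6 adjusted over the list alone; median -0.39, adjusted p = 9.93e-06, p(est) = 0.158), with Mycn at -1.49, Mllt3 at -1.40, Angpt1 at -1.35 and the transcription factor Mecom at -1.09. The HOXA9 and MEIS1 programme had 4 of 21 negative (9 and 2 positive adjusted over the list alone; median -0.20, adjusted p = 0.000509), and its call held with an estimated correlation (adjusted p = 0.0491). Its member Hoxa10 was at -0.88, which became 0.306 with the mean of all its probe sets. Ribosome biogenesis was negative with 0 of 22 members past the threshold (median -0.17, adjusted p = 9.93e-06, p(est) = 0.434). Erythroid genes were negative with 1 of 21, Icam4 (4 adjusted over the list alone; median -0.47, adjusted p = 0.0248, and 0.24 at most without any of 8 arrays, p(est) = 0.761). The other 16 lists were not called (adjusted p from 0.0537 to 0.944), but the early granulocyte and MHC class II lists passed with raised values (0.0235 and 0.031). The share of called genes with a positive interaction was 29.65%, and 40.43% after quantile normalization and 45.2% with a common 75th percentile. The count was 116 without NUP98-HOXA9 replicate 2 and 75 without both replicate 5.

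A combined response was counted by 2 criteria. By limma 0 genes lay beyond either oncogene, and 188 did at an unadjusted p under 0.05 in the 3 tests. Quantile normalization gave 4 and the replicate number as a fixed block 16. The cooperation ratio was met by 69 genes (43 up, 26 down), none of which passed in both against BCR-ABL (lowest adjusted p = 0.0715). Of these, Adamdec1 and Htra3, chosen after their values were seen, passed in the interaction (2.37 and 2.17, adjusted p = 0.0419 and 0.0172). They differed by 0.36 and 0.39 from BCR-ABL in both and were lower in NUP98-HOXA9 than in neither.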

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

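The tests of other cell types, background values and a shared effect for the positive interactions, of a label swap, of a single misassigned array and of the gene values a mixture predicts for NUP98-HOXA9 replicate 2, of few NUP98-HOXA9 cells among those sorted for both, of Hoxa9 in both against BCR-ABL alone and the splits in a fit of only 12 arrays were chosen only after the result was seen.

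The effect of 1 oncogene differed with the other, by the interaction test of limma, for 199 genes. The largest positive values were 5.383 for Cd3e, 4.806 for Cxcl12, 4.763 for Cyp1b1, 4.193 for Mmp13, 4.174 for Igkv14-111, 4.166 for Trbv1, 4.15 for Klrc1, 3.89 for Gzma, 3.857 for Klrb1a and 3.744 for Ncr1. The largest negative values were -3.056 for Ildr2, -2.752 for Gsta3, -2.64 for Hoxb6, -2.226 for Mab21l2, -2.122 for Rab40b, -1.941 for Hoxc5, -1.877 for Lypd6b, -1.831 for Dsp, -1.754 for Icam4 and -1.723 for Nefh. The order is uncertain: raised values put Igkv14-111 (3.949) and Gzma (3.89) first of these, and Ncr1 and Ildr2 did not pass. List medians with a called interaction were -0.394 for stem markers, -0.199 for the HOXA9 and MEIS1 programme, 0.118 for cell cycle, 0.512 for monocyte, -0.465 for erythroid, 1.025 for B, 2.185 for T and NK, 0.204 for stromal and -0.17 for ribosome biogenesis genes. With an estimated correlation the calls of the HOXA9 and MEIS1 and the T and NK lists held (adjusted p = 0.0491 each) and those of the other 7 were lost (adjusted p from 0.158 to 0.761). As many genes were called in 2 of 100 splits of the 24 arrays, the real one included (2607 in the other). These splits also break up the single-oncogene effects, so they do not test the interaction alone.

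The 59 genes with a positive interaction were weighed as a first pattern. The background was not the whole cause: 30.5% of them had means at or under it in all 3 oncogene groups, and 47 of 59 stayed past the threshold with values raised to it. Other cell types in neither may account for some. That 76.3% were highest there and fell with each oncogene alone does not test this, as a positive interaction favours that shape. The T and NK, B and stromal lists held 4, 1 and 1 of the genes where chance gives 0.0551, 0.0616 and 0.0584. Gzma and Ccl5, abundant T and NK genes, had log2 levels of 10.40 and 10.23 in neither and 5.85 and 8.29 in both. Of the 17 list genes 16 lay above background in neither and 10 in both, and their mean varied within neither (6.33 to 8.21). But Thy1 was lower in neither (10.01) than in both (12.06), and the sort for lineage-negative cells should remove most mature lymphocytes. A shared effect of each oncogene on the marked cells cannot be told apart, since marked and unmarked cells differ.

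NUP98-HOXA9 replicate 2, which lay near the arrays with BCR-ABL on component 1, was a second pattern. The tables argue against a swap of labels, since the lowest of the 12 arrays of BCR-ABL and both on the axis from NUP98-HOXA9 (0) to both (1) was at 0.824. They argue, by a modest margin, against a single array of cells with both under this label, since its position was 0.717 where the 6 arrays of both lay between 0.824 and 0.993 (SD 0.0626). BCR-ABL cells mixed into the sample stay open: genes higher and genes lower in both gave shares of 0.697 and 0.641, a difference of 0.0559 (bootstrap range 0.00344 to 0.157), and the median deviation from a mixture with both was 0.992 SD over 837 genes (other arrays from their groups up to 1.1) and from one with BCR-ABL 0.98 SD over 1024 genes (up to 1.02). Against it, 7.65% and 4.39% of these genes deviated by over 3 SD where the other arrays reached 4.06% and 3.12%, Il2ra, at 11.92, lay above all arrays of BCR-ABL and both (highest 11.42), Kit and Cd34, at 11.14 and 11.86, lay among the other NUP98-HOXA9 arrays, and no biological explanation was tested.

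The few genes that separated both from BCR-ABL were another pattern. A larger spread is argued against: the median standard error was 1.02 times that of NUP98-HOXA9 against neither. Across the 1062 genes called with NUP98-HOXA9 against neither, the slope of the change on the BCR-ABL background was 0.164 (0.139 to 0.192 with 1 array left out), and 0.196 over the 961 above background in BCR-ABL. It tests no cause. Of the genes that fell, 81 had means at or under the background in BCR-ABL already. A smaller effect of NUP98-HOXA9 with BCR-ABL present and few NUP98-HOXA9 cells among those sorted for both cannot be told apart. Of the 1062 genes 64.8% moved the same way. Hoxa9 was higher in all 6 arrays of both than in all 6 of BCR-ABL (0.169 and 0.696 by probe set). Against NUP98-HOXA9 it had -0.216 and -0.096. The latter goes against few such cells only if it reads the fusion, which is unknown.

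Of 288 groups of 6 values, 15 held an array far from the others, and chance flags about 1 in 20 groups. BCR-ABL replicate 2 had a component 3 score of 4.55, the others -16.7 to -10.6. Neither replicate 1 had list means of 12.4 for early granulocyte genes (others 12.6 to 12.7) and 7.46 for megakaryocyte genes (7.95 to 8.12), and NUP98-HOXA9 replicate 2 one of 10.2 for monocyte markers (10.9 to 11.2) and a Hnmt level of 8.5 (9.08 to 9.34). Other log2 levels apart from their group were 10.9 for Bcr in both replicate 2, 10.1 for Abl1 in neither replicate 6, 2.17 and 2.92 for Plg in BCR-ABL replicate 6 and both replicate 5, 4.83 and 3.55 for Epha3 in neither replicate 6 and NUP98-HOXA9 replicate 1, 7.57 for Gsta3 in both replicate 4, 0.163 for Igk-V21 in NUP98-HOXA9 replicate 1, 6.64 for Kcnq3 in neither replicate 5 and 5.57 for Ildr2 in both replicate 6.

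Probe sets outside the gene comparisons also carried signal. The control probe set for pyruvate carboxylase had a mean intensity of 462 ± 75.7 (SD, n = 6) in BCR-ABL, 67.4 ± 16.3 in neither, 232 ± 259 in NUP98-HOXA9, where replicate 2 had 756, and 383 ± 79.6 in both. Of 10092 probe sets without a single gene, 1546 changed in BCR-ABL against neither, 315 up and 1231 down.

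For the other counts, only the real one of 100 splits of the arrays compared gave as many genes. In this fit of all 24 arrays chance is unlikely if arrays are independent. The counts were 4910 for BCR-ABL against neither (highest other 1931), 1062 for NUP98-HOXA9 against neither (3) and 3806 for both against neither (580). They were 23 for both against BCR-ABL (2), 2371 for both against NUP98-HOXA9 (1542) and 3609 for BCR-ABL against NUP98-HOXA9 (2187). In a fit of only the 12 arrays of both and BCR-ABL, 6 of 100 splits matched the 1 gene called. Chance is not excluded for that comparison. The cooperation ratio was met by 69 genes in the real split and 0 in the others. Those splits break up the single-oncogene effects it needs, so they do not test it against additive effects. The count of 0 beyond either oncogene was reached in all 100.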

How the results depend on the processing

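The setting with values raised to the background and the count without NUP98-HOXA9 replicate 2 were chosen after seeing the data; the cause of each change below was not tested, except that counting every probe set tests more features, a 2-fold minimum or another ratio limit changes the criterion, and leaving arrays out leaves fewer samples. Low signal limits the dim genes: the median within-group SD was 0.72 up to a log2 level of 4.15 and 0.117 above 10. Of 719 results for named genes, 711 kept their call and direction with trend and robust options, 701 with quantile normalization, 685 with values raised to the background and 668 with the mean of all probe sets, where 46 calls were lost, Klk1 and Bop1 in BCR-ABL against NUP98-HOXA9 reversed to -0.039 and -0.092 (from 0.29 and 0.28) and Hoxa10 in the interaction to 0.306. In the order of the comparisons, 11 of 111, 14 of 54, 5 of 104, 9 of 10, 26 of 90 and 21 of 110 named gene calls, and 11 of 35 for the interaction, were lost without at least 1 of the arrays.

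Counting every probe set gave 9739 for BCR-ABL against neither, 8584 for both against neither, 5978 for both against NUP98-HOXA9, 7071 for BCR-ABL against NUP98-HOXA9, 136 for the cooperation ratio and 3 beyond either. Quantile normalization, a common median and a common 75th percentile gave 37, 47 and 42 for both against BCR-ABL and 4, 4 and 3 beyond either. Beyond either was 1 with the mean of all probe sets, 1 without dim genes and 1 with values raised to the background. Without dim genes the interaction had 366. Array weights gave 41 for both against BCR-ABL, 3601 for both against NUP98-HOXA9 and 4 beyond either. The fit of only the groups compared gave 1 for both against BCR-ABL. A 2-fold minimum left 1471, 399, 1282, 7, 740 and 1076 for the comparisons of 2 groups and 109 for the interaction. A ratio limit of 0.8 gave 34 and of 1 gave 109. An estimated correlation left 0 lists in all comparisons except NUP98-HOXA9 against neither, with 2, and the interaction, with 2, and fry called 0 in both against BCR-ABL and 4 in the interaction. Split controls gave a correlation of 0.354.

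The samples were treated as sharing only a replicate number: over 36 same-number pairs the deviations correlated between 0.0064 and 0.28, 9 were at or under 0.1, and 23 of 24 arrays correlated best with their own number, a hint from the data and not from the design. The replicate number as a fixed block gave 2127 for NUP98-HOXA9 against neither, 158 for both against BCR-ABL (58.23% of them higher, against 86.96% of the 23), 3847 for both against NUP98-HOXA9, 1083 for the interaction and 16 beyond either. As a random block it gave 1812, 101, 681 and 12 for the same counts without both against NUP98-HOXA9.

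With each array left out in turn the counts ran from 4126 to 5010 (BCR-ABL against neither), 873 to 1122 (NUP98-HOXA9 against neither), 3170 to 3973 (both against neither), 3 to 56 (both against BCR-ABL), 1693 to 3035 (both against NUP98-HOXA9), 2787 to 4144 (BCR-ABL against NUP98-HOXA9), 75 to 273 (interaction), 0 to 2 (beyond either) and 53 to 93 (cooperation ratio), the lists called from 16 to 19, 9 to 12, 17 to 21, 3 to 8, 12 to 17, 16 to 17 and 8 to 13, and the correlation from 0.408, without NUP98-HOXA9 replicate 2, to 0.559. Without that array the ratio count was 93 and the interaction 116. Both against BCR-ABL moved over 1.5 times without neither 4 (15) and 6 (14), BCR-ABL 1 (5), 3 (56), 4 (11), 5 (11) and 6 (5), NUP98-HOXA9 5 (12) and both 1 (10), 2 (9), 3 (4), 4 (8), 5 (3) and 6 (14). The interaction did without neither 1 (127) and 3 (121), BCR-ABL 2 (96), 4 (90) and 6 (101), NUP98-HOXA9 2, 3 (128) and 6 (109) and both 1 (123), 3 (89), 4 (108) and 5 (75). Beyond either was 1 without BCR-ABL 2, NUP98-HOXA9 1 or 2 or both 2 or 6, and 2 without BCR-ABL 3. Lists in both against BCR-ABL were 3 without BCR-ABL 6 and 4 without both 4.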
